A study of Rattus norvegicus with 60 samples.

How the data were processed

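RNA from CA1, CA3, the dentate gyrus (DG) and whole hippocampus of F344BN F1 rats was hybridized to Illumina rat bead arrays. Per the labels, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I, checked on a Bioanalyser and made into biotinylated cRNA with an Ambion TotalPrep kit. There were 60 arrays, on 5 slides of 12. CA1, CA3 and DG held 4 adult, 4 aged intact and 4 aged impaired samples each, on a slide of their own. Whole hippocampus held 6 adult, 9 aged intact and 9 aged impaired samples, mixed over 2 slides. Samples were grouped by region and age group as their labels give them, with adults at 12 and aged rats at 24 months.

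The deposited non-normalized table gave, per the file headers, a mean bead signal, a linear intensity, and a detection p-value for each probe and array. The deposited processed table gave a second intensity for each probe and array, and the software and settings behind it were not given in the sources used here. Within each array these processed values were a linear function of the raw signal (largest residual 0.021), had the same mean on all arrays and fell below 0 on every array. They were therefore on a linear scale, and which background was subtracted stayed unknown. Their median per array ran from 13.2 to 33.38. The table held 22523 probes, and a further 3174 lines held no probe and no value. Median raw signal per array ran from 54.45 to 128.46. All columns of values belonged to a sample.

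Gene symbols came from the probe annotation, brought up to date with a gene table of the rat. Of the probes, 10164 had a current symbol, 1665 were updated by gene number, 5050 by synonym, 5527 were kept as given and 117 had none. A symbol other than a LOC or RGD name was held by 17010 probes, and 787 such symbols had more than 1 probe. C3, C4a and Dcx had no probe of that name, and C4-2 was taken as C4b.

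Raw signals were processed in R 4.3.3 with limma 3.58.1. Its neqc function corrected the background with negative controls inferred from the detection p-values, added an offset of 16, quantile normalized all 60 arrays together and took log2. A probe was tested in CA1, CA3 or DG when detected at p under 0.01 on at least 4 arrays of the region, and in whole hippocampus on at least 6. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

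Each region was fitted with limma (lmFit and eBayes) on its 3 groups, with slide as a term in whole hippocampus. Aged against adult was the mean of intact and impaired minus adult, and the other contrast was impaired minus intact. All tests were two-sided, with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. Differences between subregions came from an F test in 1 fit of the 36 CA1, CA3 and DG arrays, followed by the pairwise differences. Common probes were those called in 1 direction in the 3 separate fits. Arrays in a direction are the aged arrays on that side of the adult mean, or the impaired arrays on that side of the intact mean. Where no array of a compared group detected a gene, its fold change was taken against the detection floor and given as a lower bound.

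The 34 gene lists were tested with limma's camera function at a preset correlation of 0.01, with the brightest probe per gene and at least 5 measured genes, and again with an estimated correlation. The 266 tests over 8 contrasts were adjusted together. The lists covered immune, glial, vascular, neuronal, subregion, metabolic and stress genes, with markers of blood, meninges, choroid plexus and neighbouring tissue. Some share genes. Astrocyte reactivity had 12 of 34 symbols in another list, glucocorticoid response 7 of 27, meninges 6 of 33, complement 3 of 33, class II 1 of 16, resting microglia 2 of 41 and reactive microglia 0 of 43. The ribosomal list was defined by symbol and took 167 symbols, among them pseudogene and like names. Ribosomal kinases and a binding protein that the symbol rule would have taken were left out after the rule was fixed.

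The comparisons, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said. The rule named, per region, the 6 highest and 6 lowest differences past the threshold in aged against adult among genes with a symbol. For impaired against intact it named the 5 highest and lowest past the threshold or, where fewer than 10 passed, those and the 5 with the smallest p. It also named up to 15 common genes, the 6 with the smallest F test p, up to 3 members of each called list, and a fixed set of genes in every region. Members of called lists are given for a selection of the lists, and some genes that the rule names are not reported here. The 3 DG probes with LOC names were added after their values were seen.

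The alternatives were log2 of the signals without background correction (signals under 1 set to 1), the processed values, each region normalized alone, no detection filter, detection on every array of the region, 1 fit over all arrays, the replicate number as a block, array weights, and leaving out each replicate of CA1, CA3 and DG. Whole hippocampus was also fitted without the slide term, on each slide alone and with array position as a covariate. Adult and aged rats had the same mean position there, so that covariate could not move the age difference. The value of 16 added to the processed values before log2 was chosen after the data were seen. Further alternatives chosen then left out CA1 adult replicate 4 before normalization, whole hippocampus impaired replicate 5, impaired replicate 9, and whole hippocampus intact replicates 2 and 7.

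The procedure was tested on simulated data made from the means and residual spread of these probes, with changes of 0.5, 1 and 2 log2 in 67, 67 and 66 probes. In aged against adult it recovered 5.97%, 31.3% and 86.4% in CA1, 76.1%, 100% and 100% in CA3, 40.3%, 85.1% and 100% in DG and 82.1%, 100% and 98.5% in whole hippocampus, with 3, 9, 4 and 10 false calls. In impaired against intact it recovered 2.99%, 35.8% and 75.8% in CA1, 68.7%, 98.5% and 100% in CA3, 23.9%, 74.6% and 100% in DG and 83.6%, 97% and 100% in whole hippocampus, with 4, 12, 12 and 14 false calls. The subregion F test recovered 13.4%, 56.7% and 97%, with 4 false calls. For it the changes were rises in DG alone, and each probe had the same spread in all subregions. The real spread differed between subregions, so these rates may not carry over to the real arrays. Of 66 simulated list tests, the 1 shifted list was called and 0 others. The simulated probes were drawn independently, so the effect of correlation between the genes of a list was not tested.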

Results

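Gene expression was measured on Illumina bead arrays in the hippocampus of F344BN F1 hybrid rats, a cross often used in studies of ageing. The series asked which age-related changes the parts of the hippocampus share and which are specific to a part. Tissue came from CA1 and CA3, which hold the pyramidal neurons of the hippocampus proper, from the dentate gyrus (DG), which holds the granule neurons, and from whole hippocampus. Each region had adult rats of 12 months and aged rats of 24 months, and the aged rats were divided by their labels into intact and impaired. CA1, CA3 and DG had 4 arrays per group. Whole hippocampus had 6 adult, 9 aged intact and 9 aged impaired arrays. The labels did not say on what measure rats were called intact or impaired. Nothing tied the samples to separate animals, so the p-values measure only the spread between these samples. Between 40.64% and 47.21% of probes were detected on 59 of the 60 arrays, and 22.22% on CA1 adult replicate 4. The number of arrays limits the precision of every value below. Differences are on the log2 scale with their standard error, and adjusted p-values come from limma unless a gene list is named, when they come from limma's camera test.

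The dissection was checked with genes known to mark the subregions. Of 49 measured markers, 34 were highest in their own subregion and passed the threshold against both others, with 10 of 13 for CA1, 10 of 16 for CA3 and 14 of 20 for DG. Wfs1, a marker of CA1 pyramidal neurons, had a mean log2 intensity of 9.70 in CA1, 6.59 in CA3 and 5.90 in DG. Nectin3, an adhesion molecule, had 5.25, 7.94 and 6.48 in the same order. C1ql2, a synaptic protein of granule neurons, had 6.27, 6.13 and 9.92, and Prox1, a transcription factor of the same neurons, had 5.59, 5.50 and 7.05. Htr1a, listed for CA1, was highest in DG at 7.78, and Coch, listed for CA3, was highest in CA1 at 6.43. Each subregion lay on a slide of its own, so region and slide cannot be told apart.

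In CA1, the genes that rose in aged rats were those of MHC class II antigen presentation, with a complement inhibitor and a secreted peptide. RT1-Ba, a class II chain, rose by 2.76 ± 0.31 (6.76-fold, adjusted p = 0.00521), Cd74, the invariant chain that escorts class II molecules, by 2.34 ± 0.21 (5.05-fold, adjusted p = 0.00148) and RT1-Da, another class II chain, by 1.88 ± 0.19 (3.68-fold, adjusted p = 0.00298). Serping1, the C1 inhibitor of the complement cascade, rose by 1.17 ± 0.15 and Ecrg4, which encodes a secreted peptide of choroid plexus and other tissues, by 1.13 ± 0.15 (adjusted p = 0.0162 for each). All 8 aged arrays lay above the mean of the 4 adult arrays for each of these 5 genes, and Cd74 was detected on 1 of the 4 adult arrays. In the processed values RT1-Ba (2.86, adjusted p = 0.081), Serping1 (1.28, adjusted p = 0.166) and Ecrg4 (1.19, adjusted p = 0.147) lost their calls, and Ecrg4 lost it without background correction (0.69, adjusted p = 0.0785).

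Of the 6 measured class II genes in CA1, 3 rose over all probes tested and 4 adjusted over the list alone, with a median of 1.573 (adjusted p = 6.18e-07, and adjusted p = 0.0688 with an estimated correlation). The complement list had a median of 0.24 over 19 genes (adjusted p = 0.00487, and adjusted p = 0.123 with an estimated correlation), with 1 gene over all probes and 2 adjusted over the list alone. Astrocyte reactivity genes had a median of 0.279 over 17 genes (adjusted p = 0.00138, and adjusted p = 0.081 with an estimated correlation), with 1 and 5 respectively. C4b, complement component 4, which both lists hold, was at 0.89 ± 0.17 (adjusted p = 0.234) and Gfap, the astrocyte intermediate filament, at 0.80 ± 0.25 (adjusted p = 0.63), each higher in 8 of 8 aged arrays. Complement and astrocyte reactivity both lost their calls without adult replicate 2 (adjusted p = 0.0863 and 0.0536), and over probes detected on every CA1 array their medians were -0.021 (adjusted p = 0.363) and -0.056 (adjusted p = 0.777). Without adult replicate 4 they were 0.334 (adjusted p = 4.58e-05) and 0.439 (adjusted p = 5.99e-06), with Gfap at 0.45.

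Markers of other cell types and housekeeping groups moved in CA1 in the same direction, without a member past the threshold over all probes or adjusted over the list alone. Ribosomal proteins had a median of 0.459 over 92 genes (adjusted p = 5.84e-05, and adjusted p = 0.444 with an estimated correlation). Lysosomal genes had 0.516 over 36 (adjusted p = 0.00397, and adjusted p = 0.433 with an estimated correlation), as in the lysosomal cholesterol carrier Npc2 at 0.86 ± 0.25. Oligodendrocyte and myelin genes had 0.341 over 40 (adjusted p = 0.00133, and adjusted p = 0.57 with an estimated correlation), with Mbp, myelin basic protein, at 0.72 ± 0.51 and Klk6, a protease of oligodendrocytes, at 0.74. Resting microglial markers had 0.16 over 24 (adjusted p = 0.0482, and adjusted p = 0.32 with an estimated correlation), as in the Fc receptor Fcgr3a at 0.82. Astrocyte markers had 0.419 over 25 (adjusted p = 0.0211, and adjusted p = 0.738 with an estimated correlation), as in S100b at 1.20 ± 0.37. Antioxidant genes had 0.29 over 38 (adjusted p = 0.0111, and adjusted p = 0.639 with an estimated correlation) and oxidative phosphorylation genes 0.259 over 73 (adjusted p = 0.0252, and adjusted p = 0.738 with an estimated correlation). Ndufb4, a subunit of respiratory complex I, read 0.63 with its brighter probe and -0.35 with the other.

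Of these 7 CA1 groups, 3 lost their calls without adult replicate 4, the array of few detected probes. Without adult replicate 4 the astrocyte median was -0.024 (adjusted p = 0.956), the oxidative phosphorylation median 0.01 (adjusted p = 0.879) and the antioxidant median 0.049 (adjusted p = 0.212). The others kept theirs without it, at 0.126 for ribosomal proteins (adjusted p = 8.98e-05), 0.145 for lysosomal genes (adjusted p = 0.00192), 0.082 for oligodendrocytes (adjusted p = 0.0199) and 0.245 for resting microglia (adjusted p = 4.01e-05). In the processed values the antioxidant, astrocyte, lysosomal and oxidative phosphorylation calls were lost (adjusted p = 0.0834, 0.111, 0.056 and 0.424). The astrocyte call was also lost without impaired replicate 4 (adjusted p = 0.0649), and the oxidative phosphorylation call without adult replicate 2 (adjusted p = 0.0614) or impaired replicate 3 (adjusted p = 0.0529). Without adult replicate 4, Mbp was at 0.03, Npc2 0.51, Klk6 0.42, Fcgr3a 0.51, S100b 0.67 and the brighter probe of Ndufb4 0.37.

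The resting microglia call in CA1 was lost over probes detected on every array (0.109, adjusted p = 0.227) and with each region normalized alone (0.157, adjusted p = 0.0513). It was also lost without any of 10 arrays, with a highest adjusted p of 0.365. These were adult replicates 1, 2 and 3, intact replicates 3 and 4 and impaired replicates 1 and 4 of CA1, and, through the shared adjustment, adult replicate 1 and impaired replicates 1 and 4 of DG. Over 9978 probes 5 were called higher and 0 lower by limma, with 606 at an unadjusted p under 0.05. The count was 11 without adult replicate 4. It was 3, with Serping1 and Ecrg4 lost at adjusted p between 0.0542 and 0.1, without adult replicate 1 or 2, intact replicate 1 or impaired replicate 1, 2 or 4, and 4, with Ecrg4 lost at 0.0512, without intact replicate 4. Other fixed genes stood at 0.65 ± 0.32 (B2m, the light chain of MHC class I), 0.16 ± 0.19 (Aif1, a microglial marker), 0.35 ± 0.33 (Sst, somatostatin) and 0.06 ± 0.28 (Bdnf, a growth factor). They stood at -0.03 ± 0.27 (Arc, an activity-regulated gene), -0.05 ± 0.13 (Calb1, calbindin) and -0.94 ± 0.56 (Ttr, transthyretin, abundant in choroid plexus), with all 7 at adjusted p between 0.63 and 0.96. Without adult replicate 4, B2m was at 0.17, Aif1 0.37, Sst -0.13, Bdnf -0.28, Arc -0.34, Calb1 -0.11 and Ttr -0.78 (adjusted p between 0.178 and 0.538), and Ttr was at -0.28 without adult replicate 1 and -1.40 without adult replicate 2.

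In CA3, 77 probes rose and 13 fell in aged rats among 9873. Class II genes again had the highest values, with RT1-Ba at 1.74 ± 0.23 (3.34-fold, adjusted p = 0.00166), Cd74 at 1.67 ± 0.19 (3.18-fold, adjusted p = 0.000576), RT1-Db1 at 1.66 ± 0.18 (3.16-fold, adjusted p = 0.000576) and RT1-Da at 1.60 ± 0.22 (3.02-fold, adjusted p = 0.00282). Serping1 rose by 1.12 ± 0.13 (adjusted p = 0.000576), S100a4, a calcium-binding protein, by 1.07 ± 0.17 (adjusted p = 0.00723), Ecrg4 by 0.74 ± 0.11 (adjusted p = 0.00415) and Gfap by 0.68 ± 0.08 (adjusted p = 0.000584). Cd68, a lysosomal protein of phagocytes, rose by 0.82 ± 0.10 (adjusted p = 0.00105). It was detected on 0 of 4 adult arrays, and the aged mean was at least 1.24-fold above the detection floor of the adult arrays. Every named CA3 gene that rose was above the adult mean in 8 of 8 aged arrays.

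Microglial and immune groups rose together in CA3. Resting microglial markers had a median of 0.249 over 23 genes, 22 of them above 0 (adjusted p = 6.44e-13, and adjusted p = 0.00365 with an estimated correlation), with 5 genes called over all probes and 16 adjusted over the list alone. Among them were Trem2, a lipid-sensing receptor of microglia, at 0.52 ± 0.07 (adjusted p = 0.00282) and Fcgr3a at 0.48 ± 0.08 (adjusted p = 0.00749). Reactive microglial markers had 0.341 over 18 (adjusted p = 1.51e-11, and adjusted p = 0.0251 with an estimated correlation), with 7 higher over all probes, and 9 higher and 1 lower adjusted over the list alone. Ncf1, a subunit of the phagocyte NADPH oxidase, rose by 0.71 ± 0.08 (adjusted p = 0.000576). Complement genes had 0.334 over 19 (adjusted p = 5.67e-10, and adjusted p = 0.0222 with an estimated correlation), with 5 over all probes and 12 adjusted over the list alone, among them C1qa, a chain of C1q, at 0.51 ± 0.06 (adjusted p = 0.00108). C4b was at 0.62 ± 0.15 (adjusted p = 0.0762). The 6 class II genes had a median of 1.628 (adjusted p = 1.43e-11, and adjusted p = 0.0597 with an estimated correlation), with 5 called by either adjustment.

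Astrocyte reactivity genes rose in CA3 with a median of 0.414 over 17 genes (adjusted p = 1.23e-08, and adjusted p = 0.0255 with an estimated correlation), 5 over all probes and 9 adjusted over the list alone. Lysosomal genes had 0.129 over 36 (adjusted p = 1.31e-05, and adjusted p = 0.0315 with an estimated correlation), with 3 and 7, among them Npc2 at 0.49 ± 0.06 (adjusted p = 0.00184) and the protease Ctsc at 0.43 ± 0.08 (adjusted p = 0.0171). Oligodendrocyte and myelin genes had 0.183 over 40, 37 of them above 0 (adjusted p = 5.67e-07, and adjusted p = 0.486 with an estimated correlation), with 1 and 9. The called member was Hapln2, a matrix link protein of nodes of Ranvier, at 0.53 ± 0.10 (adjusted p = 0.0199), and Mbp was at 0.44 ± 0.13 (adjusted p = 0.162), and 0.24 without adult replicate 1. MHC class I genes had 0.073 over 20 (adjusted p = 0.0102, and adjusted p = 0.368 with an estimated correlation), with 1 and 1. That gene was Psmb8, an immunoproteasome subunit, at 0.44 ± 0.08 (adjusted p = 0.0106), which the astrocyte reactivity list also holds. Ribosomal proteins had 0.063 over 92 (adjusted p = 0.00127, and adjusted p = 0.081 with an estimated correlation), with 0 by either adjustment.

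The synaptic vesicle and GABA signalling lists fell in CA3 with the preset correlation. Synaptic vesicle genes had a median of -0.075 over 37 (adjusted p = 0.029, and adjusted p = 0.625 with an estimated correlation), with 1 lower over all probes and 2 adjusted over the list alone. Syn1, synapsin I, fell by 0.37 ± 0.08 (adjusted p = 0.0471), and Snap25, a SNARE protein, was at -0.27 (adjusted p = 0.163). GABA signalling and interneuron genes had -0.11 over 39 (adjusted p = 0.0197, and adjusted p = 0.578 with an estimated correlation), with 0 by either adjustment. Of its members, the receptor subunit Gabbr2 was at -0.20, and the neuropeptide Cort and the cannabinoid receptor Cnr1 were at 0.30 and 0.23 (adjusted p = 0.273, 0.23 and 0.325). The other genes with the lowest values past the threshold were Ebag9 at -0.59 ± 0.13 (adjusted p = 0.0459) and Zfp763 at -0.59 ± 0.10 (adjusted p = 0.0106). Zfp763 was detected on 4 of 4 adult and 0 of 8 aged arrays, so it was at least 1.15-fold lower. The membrane haem-binding protein Pgrmc1 was at -0.56 ± 0.10 (adjusted p = 0.0167) and the glycine receptor subunit Glra2 at -0.54 ± 0.08 (adjusted p = 0.00663). Rgs4, a regulator of G protein signalling, was at -0.41 ± 0.09 (adjusted p = 0.0411) and Zfp455 at -0.38 ± 0.08 (adjusted p = 0.0269). Each of these 6 was lower in 8 of 8 aged arrays. Ebag9 and Zfp455 were each detected on 4 of 4 adult, 1 of 4 intact and 0 of 4 impaired arrays, so their sizes depend on the detection floor. Aif1 was at 0.34 ± 0.08 (adjusted p = 0.0764), and the other fixed genes lay between -0.24 ± 0.10 for Bdnf and 0.15 ± 0.07 for B2m. Without adult replicate 1, 2 or 4 the CA3 count was 53, 52 or 43 in place of 90, and 1364 probes were at an unadjusted p under 0.05.

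Several CA3 calls near the threshold were lost without single arrays. Syn1 lost its call without any array but intact replicate 3 (highest adjusted p = 0.154) and Rgs4 without any but intact replicate 4 and impaired replicate 3 (0.128). Ebag9 lost it without any but adult replicate 3, intact replicate 4 and impaired replicate 1 (0.116) and Zfp455 without any adult, intact replicates 3 or 4 or impaired replicates 2 or 3 (0.0968). Ctsc lost it without adult replicate 1, 2 or 4 (adjusted p = 0.0615, 0.069 and 0.0603), Pgrmc1 without adult replicate 1 or 4 (adjusted p = 0.0727 and 0.0768) and Hapln2 without adult replicate 4 (adjusted p = 0.0618). With no detection filter, Syn1 (adjusted p = 0.0612), Rgs4 (0.0593) and Ebag9 (0.104) lost their calls, without background correction Ebag9 (0.0613) and Zfp455 (0.0849), and in the processed values Syn1 (0.0571). In 1 fit over all arrays, which pools the spread over regions, Syn1, Rgs4, Ebag9, Zfp455, Zfp763, Pgrmc1, Glra2, Hapln2, Psmb8, C1qa and Fcgr3a had adjusted p = 1, Ncf1 0.98, Trem2 0.473, Ctsc 0.342, Npc2 0.285 and Cd68 0.194.

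Calls of CA3 lists were lost too. Synaptic vesicle genes lost their call with no detection filter (median -0.049, adjusted p = 0.163). They also lost it without adult replicate 2 or 3, intact replicate 2 or impaired replicate 1 (adjusted p = 0.214, 0.0603, 0.119 and 0.0806). GABA signalling lost it without adult replicate 1 or intact replicate 3 (adjusted p = 0.127 and 0.053) and MHC class I without adult replicate 1 or 2 (adjusted p = 0.0911 and 0.0526).

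In DG, 3 probes rose in aged rats among 10152 and 0 fell by limma, with 246 at an unadjusted p under 0.05. The files name these probes only by LOC numbers, so they lie outside the rule for named genes and were chosen after their values were seen. LOC499036 rose by 1.89 ± 0.19 (3.70-fold, adjusted p = 0.000457), LOC499029 by 1.84 ± 0.14 (3.58-fold, adjusted p = 3.15e-05) and LOC688464 by 1.49 ± 0.13 (2.80-fold, adjusted p = 0.000103), each in 8 of 8 aged arrays. In CA3 they were at 0.36 ± 0.19, 0.33 ± 0.17 and 0.36 ± 0.09 (adjusted p = 0.413, 0.412 and 0.11), and in CA1 at 1.11 ± 0.39, 0.01 ± 0.49 and 0.43 ± 0.33 (adjusted p between 0.63 and 0.993). Without CA1 adult replicate 4 the CA1 values were 0.77, 0.65 and 0.85 (adjusted p = 0.227, 0.231 and 0.168). The difference between CA3 and DG had adjusted p = 1 for each in the joint fit with CA1, and without CA1 adult replicate 4 it had adjusted p = 0.269, 0.0648 and 0.0253. In a fit of CA3 and DG alone, chosen after the values were seen, it was -1.52 ± 0.29, -1.52 ± 0.23 and -1.13 ± 0.16 for CA3 minus DG (adjusted p = 0.0577, 0.00529 and 0.00347 over all probes).

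**Figure D1:**
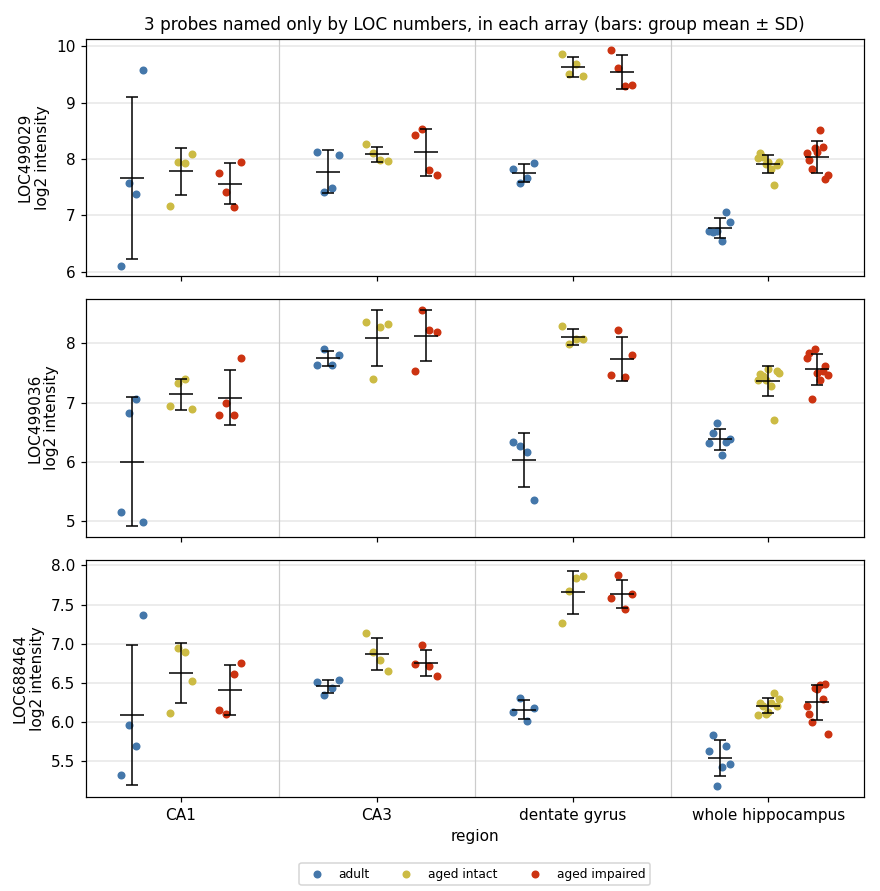
Normalized log2 intensity of LOC499029, LOC499036 and LOC688464 on each of the 60 arrays by region and age group, with a point per array and a bar for the group mean ± SD. In DG the LOC499029 means were 7.75 in adult, 9.63 in aged intact and 9.54 in aged impaired rats.

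MHC class II genes in DG had a median of 0.576 over 6 genes, each of them above 0 (adjusted p = 3.60e-10, and adjusted p = 0.0571 with an estimated correlation), with 0 over all probes and 4 adjusted over the list alone. RT1-Ba was at 0.98 ± 0.19 (adjusted p = 0.321), RT1-Da at 0.89 ± 0.17 (adjusted p = 0.268) and Cd74 at 0.63 ± 0.13 (adjusted p = 0.509), each higher in 8 of 8 aged arrays. Cd74 was detected on 0 of 4 adult DG arrays, and the aged mean was at least 1.04-fold above their detection floor. Interferon response genes had a median of 0.127 over 20 (adjusted p = 0.00251, and adjusted p = 0.0941 with an estimated correlation) and oligodendrocyte genes 0.093 over 37 (adjusted p = 0.0102, and adjusted p = 0.343 with an estimated correlation). Reactive microglial markers had 0.13 over 13 (adjusted p = 0.0142, and adjusted p = 0.414 with an estimated correlation) and resting microglial markers 0.105 over 22 (adjusted p = 0.0275, and adjusted p = 0.493 with an estimated correlation). Immediate early genes, which neurons switch on with activity, fell with a median of -0.077 over 31 (adjusted p = 0.00076, and adjusted p = 0.162 with an estimated correlation), as in the transcription factor Egr1 at -0.33 (-0.18 without adult replicate 2). Genes of proliferation and immature neurons fell with a median of -0.115 over 24 (adjusted p = 0.0119, and adjusted p = 0.201 with an estimated correlation), as in the membrane-associated Marcksl1 at -0.32, while Mcm2, a DNA replication factor, was at 0.23 in 8 of 8 aged arrays. Sox11, a transcription factor of young neurons, was detected on 3 of 4 adult, 0 of 4 intact and 2 of 4 impaired arrays, so its size of change is not given.

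In none of these 6 DG lists was a member called by either adjustment, and each lost its call without at least 1 array except the immediate early genes. The highest adjusted p after leaving out 1 array was 0.399 for resting microglia and 0.302 for reactive microglia, both without adult replicate 3, 0.136 for oligodendrocytes and 0.082 for interferon response, both without adult replicate 1, and 0.407 for proliferation, without adult replicate 2. With no detection filter, interferon response (0.043, adjusted p = 0.178) and proliferation (-0.02, adjusted p = 0.469) lost their calls. Over probes detected on every DG array, proliferation (-0.105, adjusted p = 0.0515), reactive microglia (0.09, adjusted p = 0.149) and the CA1 markers below (-0.01, adjusted p = 0.0563) did. CA1 markers moved in DG with the aged group. Their median was -0.01 and their mean -0.247 over 9 genes (adjusted p = 0.0227, and adjusted p = 0.277 with an estimated correlation), with 1 lower adjusted over the list alone, and the median was 0.014 in the processed values and 0.025 without adult replicate 1 (adjusted p = 0.239). That call was also lost without adult replicate 4, intact replicate 3 or impaired replicate 1 or 3 (adjusted p = 0.071, 0.0534, 0.059 and 0.0575). Wfs1, detected on 4 of 8 aged arrays, was at -0.99 ± 0.35 and Ccn3, a secreted matrix protein, at -0.95 ± 0.28 (adjusted p = 1 for each). Without adult replicate 4 they were at -0.46 and -0.62. Serping1 was at 0.36 ± 0.15, Gfap at 0.19 ± 0.12 and C4b at 0.42 ± 0.15. The remaining fixed genes lay between -0.22 ± 0.11 for Arc and 0.16 ± 0.14 for Bdnf, at adjusted p = 1.

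In whole hippocampus, 30 probes rose and 3 fell in aged rats among 10370, with 587 at an unadjusted p under 0.05. RT1-Ba rose by 2.52 ± 0.30 (adjusted p = 2.56e-05), RT1-Da by 2.14 ± 0.28 (adjusted p = 6.61e-05), Cd74 by 2.13 ± 0.28 (adjusted p = 1e-04) and RT1-Db1 by 1.91 ± 0.32 (adjusted p = 0.0027), each in 18 of 18 aged arrays. LOC499029 rose by 1.20 ± 0.10 (adjusted p = 9.82e-08), LOC499036 by 1.08 ± 0.10 (adjusted p = 8.19e-07) and LOC688464 by 0.69 ± 0.09 (adjusted p = 6.42e-05), also in 18 of 18. S100a4 rose by 0.87 ± 0.17 (adjusted p = 0.0103, 17 of 18), Serping1 by 0.80 ± 0.10 (adjusted p = 6.61e-05) and Hspb1, a small heat shock protein, by 0.67 ± 0.10 (adjusted p = 0.000881). Lgals3, a galectin of phagocytes, rose by 0.52 ± 0.08 (adjusted p = 0.00152), Npc2 by 0.46 ± 0.07 (adjusted p = 0.000417) and Gfap by 0.45 ± 0.08 (adjusted p = 0.00421). Serping1, Hspb1, Lgals3, Npc2 and Gfap were higher in 18 of 18. The 3 genes that fell were Igf2, an insulin-like growth factor, by 0.66 ± 0.14 (adjusted p = 0.0316), Gprasp3 by 0.56 ± 0.11 (adjusted p = 0.0195) and Plppr1, a neuronal membrane protein, by 0.25 ± 0.05 (adjusted p = 0.0412). Gprasp3 was detected on 6 of 6 adult, 2 of 9 intact and 3 of 9 impaired arrays. Cd74 and LOC688464 were detected on 2 of 6 adult arrays each and RT1-Db1 on 3 of 6. The sizes of these 4 differences therefore depend on the detection floor.

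Both slides of whole hippocampus held all 3 groups. On slides 1 and 2 alone, RT1-Ba was at 2.35 and 2.66, RT1-Da at 1.87 and 2.38, Cd74 at 2.05 and 2.18, RT1-Db1 at 1.64 and 2.15, Serping1 at 0.83 and 0.78 and S100a4 at 0.91 and 0.83. Hspb1 was at 0.67 and 0.68, Lgals3 at 0.47 and 0.55, Npc2 at 0.42 and 0.49 and Gfap at 0.45 and 0.45. LOC499029 was at 1.30 and 1.09, LOC499036 at 1.06 and 1.10 and LOC688464 at 0.62 and 0.76. Igf2 was at -0.48 and -0.85, Gprasp3 at -0.46 and -0.65 and Plppr1 at -0.24 and -0.26. RT1-Ba, RT1-Da and Cd74 passed the threshold on slide 1 alone (adjusted p = 0.000506, 4.13e-05 and 0.00116) and not on slide 2 (adjusted p = 0.159, 0.283 and 0.417). LOC499036 passed it on both (adjusted p = 0.0154 and 0.0327) and LOC499029 on slide 1 alone (0.102 on slide 2), and the others of this paragraph on neither. With no detection filter Igf2 lost its call (adjusted p = 0.0683), and in the processed values Plppr1 (0.2). In 1 fit over all arrays Gfap (adjusted p = 0.0908), Lgals3 (0.109), Hspb1 (0.18) and Trem2 (0.478) lost theirs, as did Plppr1 and Bcas1. With the replicate number as a block, Gprasp3 (adjusted p = 0.133) and Plppr1 (0.228) did. Plppr1 lost its call without the slide term (adjusted p = 0.181), as did Trem2 (adjusted p = 0.0654).

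**Figure D2:**
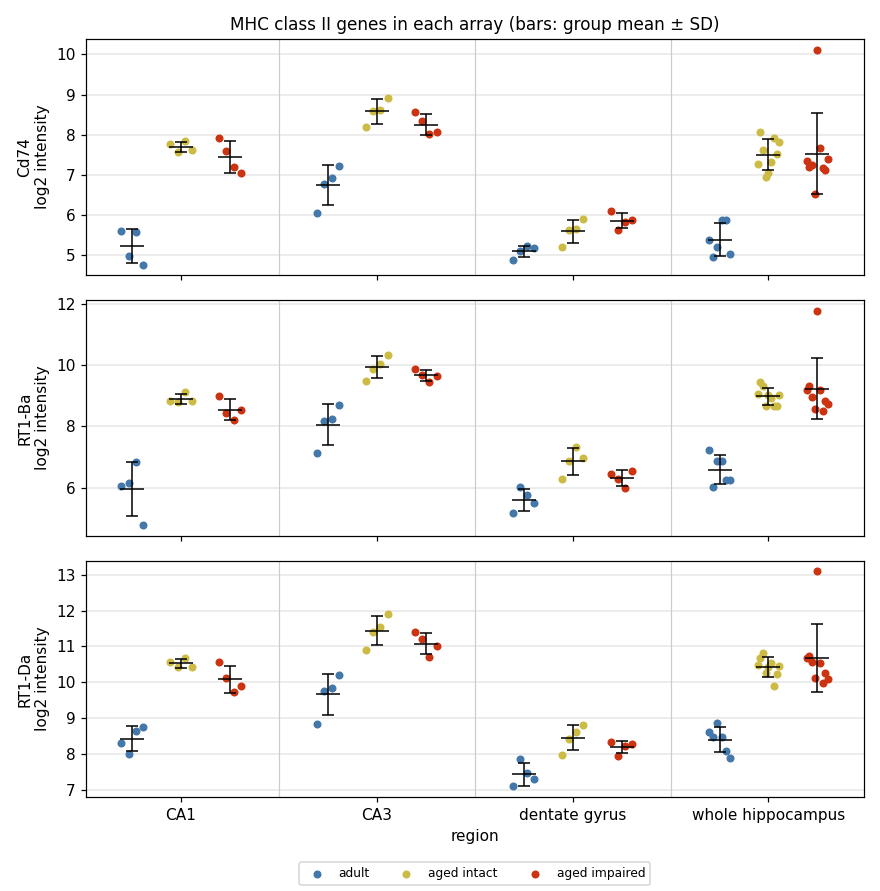
Normalized log2 intensity of Cd74, RT1-Ba and RT1-Da on each of the 60 arrays by region and age group, with a point per array and a bar for the group mean ± SD. Whole hippocampus aged impaired replicate 5 stood at 10.12 for Cd74, against 6.53 to 7.67 in the other 8 arrays of its group.

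Immune and glial gene lists rose in whole hippocampus, as did the lysosomal and antioxidant lists. Class II genes had a median of 1.905 over 7 genes (1.637 and 2.147 on slides 1 and 2, adjusted p = 1.46e-14, and adjusted p = 0.0222 with an estimated correlation), with 4 over all probes and 5 adjusted over the list alone. Astrocyte reactivity genes had 0.302 over 17 (0.261 and 0.239, adjusted p = 1.46e-14, and adjusted p = 0.000308 with an estimated correlation), with 3 and 9. Complement genes had 0.218 over 17 (0.175 and 0.251, adjusted p = 3.86e-08, and adjusted p = 0.0222 with an estimated correlation), with 1 and 6, and C4b stood at 0.96 ± 0.32 (0.90 and 0.99, adjusted p = 0.446, 18 of 18). Resting microglial markers had 0.176 over 24, each of them above 0 (0.169 and 0.194, adjusted p = 9.58e-12, and adjusted p = 0.0597 with an estimated correlation), with 1 and 6, and the called member was Trem2 at 0.37 ± 0.08 (adjusted p = 0.0315, 17 of 18). Reactive microglial markers had 0.249 over 18 (0.248 and 0.245, adjusted p = 3.62e-08, and adjusted p = 0.081 with an estimated correlation), with 1 and 7.

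Oligodendrocyte and myelin genes had 0.111 over 41 (0.185 and 0.094 on slides 1 and 2, adjusted p = 8.09e-11, and adjusted p = 0.133 with an estimated correlation), with 1 over all probes, Bcas1 at 0.35 ± 0.07 (adjusted p = 0.00848), and 12 adjusted over the list alone. Mbp was at 0.27 ± 0.12 (adjusted p = 0.789). Interferon response genes had 0.152 over 26 (0.171 and 0.213, adjusted p = 1.87e-08, and adjusted p = 0.0904 with an estimated correlation), with 25 above 0 and 0 called by either adjustment. MHC class I genes had 0.131 over 22 (0.097 and 0.118, adjusted p = 1.29e-06, and adjusted p = 0.0795 with an estimated correlation), with 0 and 3, as in RT1-A1 at 0.54 (adjusted p = 0.0973). Lysosomal genes had 0.086 over 36 (0.105 and 0.073, adjusted p = 7.85e-06, and adjusted p = 0.0538 with an estimated correlation), with 1 and 5. Antioxidant genes had 0.06 over 37 (0.04 with adjusted p = 0.103 and 0.063, adjusted p = 0.00491, and adjusted p = 0.162 with an estimated correlation), with 0 and 0. Endothelial genes were lower with a median of -0.045 over 25 (-0.052 with adjusted p = 0.216 and -0.074, adjusted p = 0.0175, and adjusted p = 0.215 with an estimated correlation), with 0 and 2, as in Ctla2a at -0.43 (adjusted p = 0.102). That call was lost with no detection filter (-0.029, adjusted p = 0.114) and over probes detected on every array (-0.043, adjusted p = 0.168). Without intact replicates 2 and 7 the median was -0.02 (adjusted p = 0.0274). Ttr stood at -1.76 ± 0.57 (adjusted p = 0.414), with -0.04 on slide 1 and -3.50 on slide 2, and the remaining fixed genes lay between -0.17 ± 0.08 for Calb1 and 0.24 ± 0.12 for Aif1.

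Shared and region-specific changes with age were then compared. CA1 and CA3 shared 5 genes called higher, Cd74, Ecrg4, RT1-Ba, RT1-Da and Serping1, against 0.04 expected of independent lists. DG shared 0 with either, so 0 of 9358 probes tested in CA1, CA3 and DG were called in all 3. CA3 and whole hippocampus shared 19 probes called higher, against 0.24 expected. Among them were Gipr, the receptor of an incretin hormone, at 0.85 ± 0.10 in CA3 and 0.71 ± 0.08 in whole hippocampus (adjusted p = 0.000576 and 2.56e-05), and Bmp7, a growth factor of the TGF-beta family, at 0.74 ± 0.07 and 0.66 ± 0.11 (adjusted p = 0.000388 and 0.00297). Gipr and Bmp7 were chosen after their values were seen. All 5 genes called in CA1 were above 0 in DG, with 4 of the 5 at an unadjusted p under 0.05. Of the 90 probes called in CA3, 83 were tested in DG. Of these, 74 had the same direction there, against 41.5 expected of independent probes, with 10 at an unadjusted p under 0.05. These expected values allow neither for probes that vary together nor for regions that share rats, which the labels leave open. Impaired, intact and adult samples held the same positions on the CA1, CA3 and DG slides, so position could also give shared directions.

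The size of the age difference was tested between the subregions in 1 fit of CA1, CA3 and DG. Of 10654 probes, 1 was called by the F test, with 742 at an unadjusted p under 0.05. This was Cd74, at 2.34 in CA1, 1.67 in CA3 and 0.63 in DG (adjusted p = 0.0238). Cd74 was detected on 0 of 4 adult arrays in DG and 1 of 4 in CA1, so its DG difference is bounded only as at least 1.04-fold and its CA1 difference depends on the detection floor. It was also the probe called for CA1 minus DG (adjusted p = 0.00506), with 1356 at an unadjusted p under 0.05. For CA1 minus CA3 or CA3 minus DG 0 were called, with 619 and 136 at an unadjusted p under 0.05. The next genes were Cd68, which 0 of 4 adult arrays detected in CA1 or CA3, at 0.58, 0.82 and -0.03 (adjusted p = 0.0701), Ybx1-ps18 at 0.70, 0.15 and -0.38 and Gpsm2, a spindle protein, at -0.67, -0.15 and 0.40 (adjusted p = 0.257 for each). Cd68 did not pass the detection filter in DG, so its -0.03 does not show whether it changes there. Spag6, a protein of cilia, was at 0.03, 0.04 and 0.55 (adjusted p = 0.281) and RT1-Ba at 2.76, 1.74 and 0.98 (adjusted p = 0.295). Spag6 did not pass the filter in CA1 or CA3, so its values there do not show a lack of change. The F test called 0 probes without any of 9 arrays, namely adult replicate 2, intact replicate 3 and impaired replicate 2 of CA1 and adult replicates 2, 3 and 4, intact replicate 1 and impaired replicates 2 and 3 of DG. It called 7 without CA1 adult replicate 1, 3 without CA1 impaired replicate 4 and 2 without CA1 adult replicate 4, CA3 impaired replicate 4 or DG impaired replicate 1. The fit pools the spread of regions whose separate fits had median standard errors of 0.259 in CA1, 0.089 in CA3 and 0.14 in DG. This can hide differences between CA3 and DG. It can also understate the spread of CA1, so p-values of contrasts with CA1, the call of Cd74 among them, may be too small. With CA3 and DG fitted alone, LOC499029 and LOC688464 passed over all probes (limma adjusted p = 0.00529 and 0.00347), and LOC499036 did not (0.0577).

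Between aged impaired and aged intact rats, no probe passed the threshold in any region. limma called 0 in CA1, CA3, DG and whole hippocampus, with 33, 500, 196 and 600 probes at an unadjusted p under 0.05. Without CA3 impaired replicate 1 it called 1 in CA3. In CA1 the named genes with the smallest p were Ptgr2, a prostaglandin reductase, at 0.57 ± 0.18, Ecrg4 at -0.55 ± 0.17, Serping1 at -0.50 ± 0.18, Nrsn1 at 0.72 ± 0.26 and Vwa8 at 0.46 ± 0.17, each at adjusted p = 1 and in the same direction in 4 of 4 impaired arrays. Vwa8 was detected on 0 of 4 intact CA1 arrays, so its size is not known. In CA3 they were Dgcr8, a microRNA-processing protein, at 0.38 ± 0.09, Mcm4, a replication helicase subunit, at 0.29 ± 0.08, Spsb2 at -0.38 ± 0.10, the peptidase Lap3 at -0.35 ± 0.09 and Fam169a at 0.39 ± 0.10 (adjusted p = 0.936, 4 of 4). Dgcr8 and Fam169a were detected on 0 of 4 intact CA3 arrays, so they were at least 1.09-fold and 1.21-fold higher. In DG they were Eps8 at 0.59 ± 0.17, Fmo1 at 0.56 ± 0.16, Gga2 at -0.78 ± 0.22, Haus7 at 0.69 ± 0.20 and Errfi1 at 0.43 ± 0.14 (adjusted p = 0.894, 4 of 4). Fmo1 was detected on 0 of 4 intact DG arrays, so it was at least 1.28-fold higher. In whole hippocampus they were Col23a1 at -0.35 ± 0.09 (-0.30 and -0.40 on slides 1 and 2), Il11ra1 at -0.30 ± 0.08 (-0.32 and -0.29), Slc44a2 at -0.31 ± 0.08 (-0.27 and -0.35), Ptgds, prostaglandin D synthase, at -0.28 ± 0.07 (-0.13 and -0.43) and Pcsk4 at 0.27 ± 0.07 (0.16 and 0.37), each at adjusted p = 0.639.

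Gene lists did pass between impaired and intact rats, with the preset correlation alone. In CA3, complement genes were lower in impaired rats with a median of -0.108 (adjusted p = 0.000117, and adjusted p = 0.081 with an estimated correlation) and reactive microglial markers with -0.144 (adjusted p = 0.000195, and adjusted p = 0.127 with an estimated correlation). Astrocyte reactivity genes were lower with -0.169 (adjusted p = 0.00138, and adjusted p = 0.127 with an estimated correlation) and resting microglial markers with -0.114 (adjusted p = 0.00169, and adjusted p = 0.081 with an estimated correlation). Adjusted over the list alone, 3 complement genes, 3 reactive microglial markers and 2 astrocyte reactivity genes were lower. Serping1 was at -0.51 ± 0.15, Cd68 at -0.42 ± 0.12 and Ncf1 at -0.32 ± 0.09, each lower in 4 of 4 impaired arrays (adjusted p = 0.936). Oligodendrocyte genes had -0.106 (adjusted p = 0.000796, and adjusted p = 0.653 with an estimated correlation), interferon response genes -0.08 (adjusted p = 0.00342, and adjusted p = 0.484 with an estimated correlation) and ribosomal proteins -0.055 (adjusted p = 0.00637, and adjusted p = 0.127 with an estimated correlation). GABA signalling and interneuron genes were higher with 0.114 over 39, 32 of them above 0 (adjusted p = 3.83e-05, and adjusted p = 0.23 with an estimated correlation), as in Slc32a1, the vesicular GABA transporter, at 0.25 ± 0.08. Interferon response lost its call without intact replicate 2 (adjusted p = 0.0871).

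In CA1, 9 lists were lower and 4 higher in impaired rats, and adjusted over the list alone 0 members of any of them were called. Immediate early genes had a median of -0.098 (adjusted p = 0.00103, and adjusted p = 0.133 with an estimated correlation). Choroid plexus and ependyma genes had -0.247, with 9 of 9 below 0 and Ttr at -1.55 ± 0.64 (adjusted p = 0.00143, and adjusted p = 0.143 with an estimated correlation). Complement genes had -0.147 (adjusted p = 0.0015, and adjusted p = 0.081 with an estimated correlation) and reactive microglial markers -0.172 (adjusted p = 0.00227, and adjusted p = 0.0795 with an estimated correlation). Class II genes had -0.316 (adjusted p = 0.00372, and adjusted p = 0.23 with an estimated correlation) and ribosomal proteins -0.092 (adjusted p = 0.00308, and adjusted p = 0.631 with an estimated correlation). Astrocyte reactivity genes had -0.128 (adjusted p = 0.00679, and adjusted p = 0.127 with an estimated correlation), interferon response genes -0.164 (adjusted p = 0.0127, and adjusted p = 0.197 with an estimated correlation) and oxidative phosphorylation genes -0.061 (adjusted p = 0.0175, and adjusted p = 0.737 with an estimated correlation). Synaptic vesicle genes had 0.138 (adjusted p = 0.00679, and adjusted p = 0.631 with an estimated correlation) and glucocorticoid response genes 0.065 (adjusted p = 0.0216, and adjusted p = 0.444 with an estimated correlation). Astrocyte markers had 0.1 (adjusted p = 0.0268, and adjusted p = 0.738 with an estimated correlation) and circadian clock genes 0.091 (adjusted p = 0.034, and adjusted p = 0.162 with an estimated correlation). With no detection filter, choroid plexus (median -0.043, adjusted p = 0.226), complement (-0.096, 0.382), class II (-0.137, 0.232), interferon response (-0.032, 0.502) and astrocyte reactivity (-0.043, 0.0875) lost their calls. So did synaptic vesicle (0.043, 0.163), glucocorticoid response (0.039, 0.178), astrocyte (0.093, 0.0897) and circadian genes (0.051, 0.0944).

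Other settings and single arrays also ended calls among these CA1 lists. Over probes detected on every CA1 array, complement (adjusted p = 0.113), interferon response (0.509), astrocyte reactivity (0.992), oxidative phosphorylation (0.2), synaptic vesicle (0.309) and astrocyte genes (0.128) lost theirs. In the processed values, astrocyte (adjusted p = 0.836), astrocyte reactivity (0.0886), glucocorticoid response (0.0617), interferon response (0.0612) and synaptic vesicle genes (0.0636) did. Without impaired replicate 4, ribosomal proteins (adjusted p = 0.517), oxidative phosphorylation (0.53) and synaptic vesicle genes (0.102) lost their calls. Class II genes (adjusted p = 0.34) and astrocyte reactivity (0.0978) lost theirs without impaired replicate 3, reactive microglia (0.0966) without intact replicate 3, and interferon response without either of these arrays (0.0612 and 0.0966). Astrocyte markers lost theirs without intact replicate 1 or 2 or impaired replicate 1 or 4 (highest adjusted p = 0.337). Circadian genes lost theirs without intact replicate 2 or 4 or impaired replicate 1 or 4 (0.109), and glucocorticoid genes without adult replicate 4, intact replicate 2 or 3 or impaired replicate 1 (0.288).

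In DG, synaptic vesicle genes were lower in impaired rats with a median of -0.136 (adjusted p = 0.0135, and adjusted p = 0.622 with an estimated correlation), with Syn1 at -1.02 ± 0.44 in 3 of 4 impaired arrays. Endothelial genes were higher with 0.155 (adjusted p = 0.0196, and adjusted p = 0.444 with an estimated correlation) and ribosomal proteins with 0.084 (adjusted p = 0.0211, and adjusted p = 0.738 with an estimated correlation). Astrocyte reactivity genes were higher with 0.136 (adjusted p = 0.0214, and adjusted p = 0.444 with an estimated correlation), as in Vim, an intermediate filament, at 0.59 ± 0.28 (0.29 without impaired replicate 1). Each of these 4 DG calls was lost without at least 1 array. The synaptic vesicle call was lost without impaired replicate 1 (adjusted p = 0.167), and the highest adjusted p of the other lists without 1 array was 0.308 for ribosomal proteins without impaired replicate 1, 0.0845 for endothelium without intact replicate 3 and 0.0749 for astrocyte reactivity without impaired replicate 4. With no detection filter, synaptic vesicle (-0.074, adjusted p = 0.136), ribosomal (0.025, adjusted p = 0.24) and astrocyte reactivity genes (0.063, adjusted p = 0.14) lost their calls. Synaptic vesicle genes lost theirs in the processed values (-0.179, adjusted p = 0.0579), and astrocyte reactivity over probes detected on every DG array (0.119, adjusted p = 0.0515). Adjusted over the list alone, 0 members were called in any of them. Array position and age group cannot be told apart on the CA1, CA3 and DG slides, where impaired, intact and adult samples each held neighbouring positions.

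In whole hippocampus, synaptic vesicle genes were lower in impaired rats with a median of -0.089 over 38, 33 of them below 0 (-0.073 and -0.112 on slides 1 and 2, adjusted p = 0.000185, and adjusted p = 0.477 with an estimated correlation). Oligodendrocyte genes had -0.039 (0.022 with adjusted p = 0.908 and -0.1, adjusted p = 0.00781, and adjusted p = 0.639 with an estimated correlation), with Mbp at -0.37 ± 0.12 in 9 of 9 impaired arrays (-0.25 and -0.49, adjusted p = 0.639). The oligodendrocyte call was lost in the processed values (-0.049, adjusted p = 0.207) and over probes detected on every array (-0.034, adjusted p = 0.0567). Immediate early genes were higher with 0.165 (0.054 with adjusted p = 0.236 and 0.193, adjusted p = 0.00076, and adjusted p = 0.407 with an estimated correlation), with 35 genes measured. Dusp1, a phosphatase induced by activity and stress, was at 0.51 ± 0.20 in 7 of 9 (0.31 and 0.72) and Junb at 0.38 ± 0.14 in 8 of 9 (0.18 and 0.58). Glucocorticoid response genes had 0.107 (0.113, and 0.094 with adjusted p = 0.0958, adjusted p = 0.0102, and adjusted p = 0.444 with an estimated correlation), and Dusp1 belongs to both of these lists. Ribosomal proteins had 0.046 (0.017 with adjusted p = 0.88 and 0.086, adjusted p = 0.0127, and adjusted p = 0.738 with an estimated correlation), and 0.026 with no detection filter (adjusted p = 0.176). Adjusted over the list alone, 0 members were called in each of these 5 lists. Without intact replicates 2 and 7, left out after the data were seen for their dim signal, the synaptic vesicle median was 0.001 (adjusted p = 0.701) and the ribosomal median -0.013 (adjusted p = 0.51). The immediate early, glucocorticoid and oligodendrocyte medians were then 0.097, 0.041 and -0.07 (adjusted p = 2.57e-05, 0.0327 and 3.35e-08). Without impaired replicate 9, also left out after the data were seen, the oligodendrocyte and ribosomal calls were lost (-0.03 and 0.032, adjusted p = 0.0609 and 0.315), and the immediate early median was 0.161 (adjusted p = 0.00774).

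**Figure D3:**
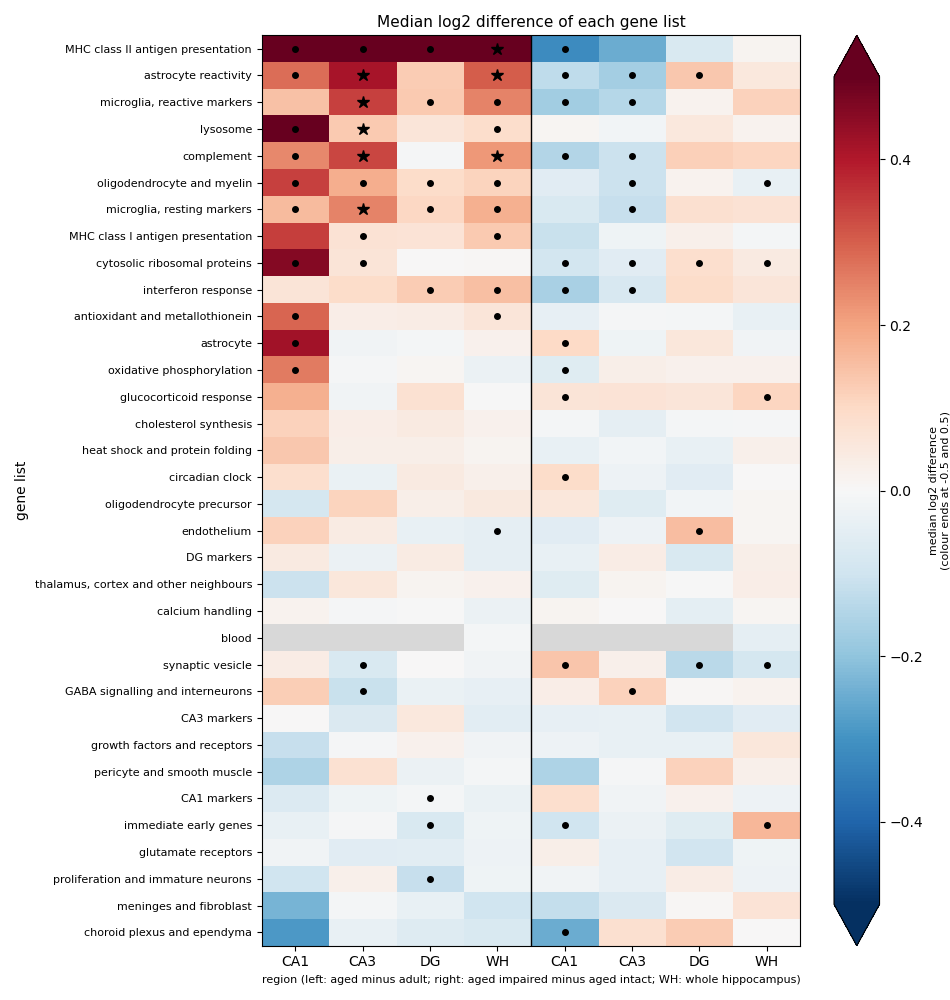
Median log2 difference of each of the 34 gene lists, aged minus adult on the left and aged impaired minus aged intact on the right, in CA1, CA3, DG and whole hippocampus (WH), with grey where fewer than 5 genes were measured. Dots mark the 70 tests past the threshold, with a star in place of the dot for the 8 that also passed with an estimated correlation, all of them higher in aged rats in CA3 or whole hippocampus.

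The impaired minus intact difference was also tested between CA1, CA3 and DG. limma's F test called 0 of 10654 probes, with 106 at an unadjusted p under 0.05. Among the genes with the smallest p were Trim14 at 0.42 in CA1, -0.12 in CA3 and -0.38 in DG, with 0 of 4 intact CA1 arrays detecting it, Ptgr2 at 0.57, 0.17 and -0.28 and Serping1 at -0.50, -0.51 and 0.25. Vwa8 was at 0.46, 0.06 and -0.25 and Ecrg4 at -0.55, -0.18 and 0.33, each at adjusted p = 1. Vwa8 did not pass the detection filter in CA3, so its 0.06 does not show whether it differs there. Lists called in 1 region and not in another were not tested for a difference between the regions.

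Of the 34 lists, 12 passed in no region and neither comparison. Their adjusted p ranged from 0.215 to 0.675 for CA3 markers, 0.303 to 0.997 for DG markers, 0.0507 to 0.952 for calcium handling and 0.269 to 0.767 for cholesterol synthesis. The range was 0.0536 to 0.825 for glutamate receptors, 0.215 to 0.879 for growth factors and receptors and 0.0934 to 0.993 for heat shock and protein folding. It was 0.0594 to 0.952 for oligodendrocyte precursors, 0.0544 to 0.952 for pericytes and smooth muscle and 0.182 to 0.997 for neighbouring tissue such as thalamus and cortex. Meninges and fibroblasts had 0.0522 to 0.993, with medians from -0.233 to 0.067. Blood, measured in whole hippocampus alone with 5 genes, had a median of -0.008 in aged against adult rats (adjusted p = 0.904) and -0.044 in impaired against intact rats (adjusted p = 0.538).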

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

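Among the tests below, those of position within whole hippocampus and in the subregions, of single arrays, of carried-over tissue, of a sequence difference, of position acting alike on both slides and of neighbouring tissue were chosen after the result was seen. Arrays far from the others of their group were sought in 204 groups of values over 17 measures, and 24 were found, against about 10.2 by chance at 1 in 20.

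CA1 adult replicate 4 stood apart in its correlation with its group, at 0.698 against 0.869 to 0.897, in Gfap at 11.88 (13.26 to 13.36), in B2m at 11.4 (13.22 to 13.45) and in Sst at 8.52 (10.43 to 10.52). Whole hippocampus impaired replicate 5 stood above its group in Cd74 at 10.12 (6.53 to 7.67), RT1-Ba at 11.78 (8.5 to 9.33), RT1-Da at 13.09 (9.97 to 10.74), RT1-Db1 at 10.28 (6.59 to 7.78), B2m at 13.98 (13.31 to 13.57), C4b at 10.75 (7.29 to 8.22) and Aif1 at 11.85 (10.58 to 10.98). Other single arrays apart in genes of the immune groups were whole hippocampus intact replicate 2 in C4b at 8.86 (7.38 to 7.87), whole hippocampus adult replicate 3 in RT1-Db1 at 6.33 (5.37 to 5.71), DG adult replicate 4 in RT1-Db1 at 5.27 (5.43 to 5.45) and in B2m at 12.68 (13.04 to 13.09), and CA1 intact replicate 3 in RT1-Ba at 9.12 (8.79 to 8.83).

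Gfap stood apart in DG impaired replicate 1 at 12.9 (13.45 to 13.46) and Sst in CA3 impaired replicate 3 at 10.23 (9.9 to 9.95). Bdnf stood apart in CA1 impaired replicate 4 at 7.75 (7.65 to 7.66), DG intact replicate 1 at 10.27 (9.82 to 9.88) and whole hippocampus adult replicate 6 at 8.97 (9.3 to 9.47). CA3 intact replicate 4 had a mean bead signal of 716.1 (627.8 to 634.3). The correlation with the group was 0.989 in CA3 impaired replicate 1 (0.993 in the others) and 0.98 in whole hippocampus impaired replicate 9 (0.987 to 0.991). Cd74 differed in its age difference between CA1, CA3 and DG (adjusted p = 0.0238 by limma's F test, with 2.34, 1.67 and 0.63), a value that depends on the detection floor, since 1 of 4 adult arrays in CA1 and 0 of 4 in DG detected it.

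MHC class II genes were higher in aged rats in all 4 regions as a list with the preset correlation, and with an estimated correlation adjusted p = 0.0688 in CA1, 0.0597 in CA3, 0.0571 in DG and 0.0222 in whole hippocampus, where RT1-DOa was at -0.10. At the 6 positions of whole hippocampus that held an adult rat on 1 slide and an aged rat on the other, their median difference was 1.97 and at single positions 1.21 to 2.23, which argues against position there, while in CA1, CA3 and DG 0 positions held both, so position and age cannot be told apart. It was 1.74 without impaired replicate 5, which argues against that array as the source. The medians of the meninges and choroid plexus lists in each region, and of blood in whole hippocampus alone, had a highest value of -0.01, so these lists did not rise with the class II genes. Blood was not measured in CA1, CA3 or DG. A list median can miss such tissue: in whole hippocampus Ttr was at -1.76 and the choroid plexus median at -0.08. Carried-over tissue is therefore not excluded. A rise with age in the cells of the hippocampus stays open, as a hypothesis found and tested on the same data, and which cells carry it was not tested.

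LOC499029, LOC499036 and LOC688464 were higher in aged DG and whole hippocampus. Their mean difference at the same 6 positions of whole hippocampus was 0.91 and at single positions 0.53 to 1.32, which argues against position there, while 0 positions held both ages in DG, where position stays open. A sequence difference under the probes between the adult and aged rats could also raise them, and was assumed to do so alike in every region. In a fit of CA3 and DG alone, 3 of the 3 probes had a smaller difference in CA3, by -1.52 ± 0.23, -1.52 ± 0.29 and -1.13 ± 0.16 (by limma adjusted p = 1.49e-06, 2.17e-05 and 9.77e-07 over the 3 probes, and adjusted p = 0.00529, 0.0577 and 0.00347 over all probes). The probes were chosen for their calls in DG, which favours a larger difference there, so this fit does not settle the question. It replaced the joint fit with CA1, where 0 of 3 passed over all probes at unadjusted p = 0.00265, 0.000875 and 0.00108. A sequence difference, a change with age and rats that differ between the regions stay open.

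The impaired minus intact differences ran in opposite directions in CA1 and DG, with a Pearson correlation of -0.572 and a Spearman correlation of -0.509 across 9623 probes. This was the strongest by size of 12 correlations, over the pairs of regions in both contrasts. Probes are not independent replicates, and splitting the 8 aged arrays of each region otherwise gave a correlation of this size in 115 of 1225 pairs of splits (exact permutation p = 0.0939), so an array-wide axis unrelated to impairment may account for it. Over 1697 probes with like levels in CA1, CA3 and DG, which tissue of a neighbouring subregion would shift little, the correlation was -0.513. An array-wide axis would reach these probes too, so this does not decide whether such tissue contributes. Tissue from outside these subregions was not covered. This test replaced one on marker medians after that had been seen. Those medians were -0.04 for DG markers in CA1, and 0.02 and -0.1 for CA1 and CA3 markers in DG. Position acting alike on both slides would give a positive correlation, not -0.572, but since chance splits reach this size, it stays open. Impairment itself stays open.

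For the counts of probes in aged against adult rats, fewer than 5 of 100 splits gave as many in each region, counting the real split. In CA1 1 split gave as many as the real 5 (highest other 0), in CA3 3 gave as many as 90 (highest other 573), in DG 3 gave as many as 3 (highest other 265) and in whole hippocampus 2 gave as many as 33 (highest other 1249). For the lists in whole hippocampus, 3 of 100 splits gave as many as the real 13 (highest other 17). For the subregion F test, 2 of 100 gave as many as the real 1 (highest other 7). Those splits shuffled the groups within each subregion, which removes the age difference from all of them. They therefore do not test whether an age difference varies between subregions. All these counts were uncommon among the splits, which does not exclude chance. More splits reached the real count for the lists in CA1, with 6 of 100 as many as 12 (highest other 15), CA3, with 6 of 100 as many as 13 (highest other 16), and DG, with 10 of 100 as many as 8 (highest other 12). Lists were adjusted within each contrast for these counts. The splits that called several times the real count in CA3, DG and whole hippocampus point to a structure of the samples, and what those splits share was not tested.

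For impaired against intact rats, the real count was 0 probes in each region, which all 35 splits in CA1, CA3 and DG and all 100 in whole hippocampus must reach, so those splits decide nothing (highest others 0, 7, 0 and 1). Nor do the 100 splits for the real 0 probes of the subregion F test (highest other 9) and, in aged against adult, for the real 0 probes common to CA1, CA3 and DG (highest other 0). For the lists chance was not excluded. Of the splits, 2 of 35 in CA1 gave as many as 16 (highest other 17), 4 of 35 in CA3 as many as 8 (highest other 12), 7 of 35 in DG as many as 4 (highest other 7) and 42 of 100 in whole hippocampus as many as 5 (highest other 13).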

How the results depend on the processing

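The settings that left out CA1 adult replicate 4 before normalization, or whole hippocampus impaired replicate 5 or 9 or intact replicates 2 and 7, were chosen after seeing the data. Of 306 gene results, 297 kept their direction and their side of the threshold without background correction, 298 in the processed values, 305 with each region normalized alone and 302 without a detection filter. Of the 70 called lists, 70, 58, 69 and 53 did. Fewer of the 306 gene results did in 1 fit over all arrays (249), with array weights (283) and with the replicate number as a block (292). Over probes detected on every array, 50 of 65 lists did. Most of the gene results were not called, so keeping their side of the threshold says little for those. The cause of the changes below was not tested unless named. The processed values moved the median of all probes in CA1 aged against adult to 0.24, from 0.064.

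The CA1 aged against adult count of 5 was 3 in the processed values, 1 over probes detected on every array, 26 with array weights and 11 when normalized again without adult replicate 4. In 1 fit over all arrays, which pools the spread over regions by construction, it was 1985, while CA3 had 12 in place of 90, DG 8 in place of 3 and whole hippocampus 17 in place of 33. Array weights gave 1 in CA1 impaired against intact and 91 in whole hippocampus aged against adult. The whole hippocampus count was 8 on slide 1 alone and 1 on slide 2 alone, with fewer arrays in each, and 64 without intact replicates 2 and 7. The subregion F test called 0 in the processed values, 2 without a detection filter and 2 when normalized again without CA1 adult replicate 4, in place of 1. With an estimated correlation, 8 of the 70 lists passed. Position could not be fitted in CA1, CA3 and DG.

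With the replicate number as a block, the CA1 count was 3. The block tested pairing by number, and 3 of 12 same-number pairs in CA1, 6 of 12 in CA3, 3 of 12 in DG, 12 of 21 in whole hippocampus and 21 of 36 across subregions had a correlation over 0.1. Across subregions the mean correlation was 0.073 for same-number pairs and -0.023 for other pairs. The numbers were not taken to pair samples, but rats shared between the subregions stay open, and the joint fit treats its arrays as independent.

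Leaving out 1 array gave counts from 3 (without adult replicate 1, among others) to 11 (without adult replicate 4) in CA1 aged against adult, 43 (without adult replicate 4) to 89 in CA3, and 3 to 3 in DG. In impaired against intact the range was 0 to 0 in CA1 and DG and 0 to 1 in CA3 (1 without impaired replicate 1). It was 0 to 0 for common probes, 0 (without CA1 adult replicate 2, among others) to 7 (without CA1 adult replicate 1) for the F test in aged against adult, 0 to 0 in impaired against intact, and 64 to 75 for lists.

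Some list medians changed sign. Astrocyte markers in CA1 aged against adult ranged from -0.024 (without adult replicate 4, and when normalized again without it, adjusted p = 0.956) to 0.531. Over probes detected on every array, astrocyte reactivity in CA1 was -0.056 and complement -0.021. CA1 markers in DG ranged from -0.072 to 0.025 (without adult replicate 1), with 0.006 and 0.013 without impaired replicate 3 or 4 and 0.014 in the processed values. In whole hippocampus impaired against intact, without intact replicates 2 and 7, ribosomal proteins were at -0.013 and synaptic vesicle genes at 0.001. The median standard error in aged against adult was 0.259 in CA1, 0.14 in DG, 0.09 in whole hippocampus and 0.089 in CA3.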

Other observations

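The values here were chosen after they were seen, and no explanation was tested for them. Genes outside the lists were also called higher in aged rats in both CA3 and whole hippocampus. C1qtnf9, a secreted protein of the C1q and TNF family, was at 0.74 ± 0.09 in CA3 and 0.53 ± 0.09 in whole hippocampus (adjusted p = 0.000669 and 0.00349). Emp3, a membrane protein, was at 0.55 ± 0.09 and 0.34 ± 0.06 (adjusted p = 0.00749 and 0.00797), and Sema3b, a secreted semaphorin, at 0.60 ± 0.11 and 0.33 ± 0.07 (adjusted p = 0.0161 and 0.0348). Aadat, an enzyme that makes kynurenic acid, was at 0.41 ± 0.08 and 0.37 ± 0.06 (adjusted p = 0.0217 and 0.000459), and Rom1, known from photoreceptors, at 0.34 ± 0.07 and 0.39 ± 0.08 (adjusted p = 0.0353 and 0.0338). In CA1, Aadat was at 1.16 ± 0.51 and Emp3 at -0.03. Whether these differences vary between regions was not tested for whole hippocampus.

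Across probes, the aged minus adult differences had a Pearson correlation of 0.526 (Spearman 0.419) between CA3 and whole hippocampus, and 0.008 (Spearman -0.013) between CA1 and DG. The impaired minus intact differences had 0.397 (Spearman 0.358) between DG and whole hippocampus and 0.293 (Spearman 0.285) between CA1 and CA3. These are 4 of 12 such pairs, and probes are not independent replicates.

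Whole hippocampus impaired replicate 9 had the highest list median of the 24 arrays in 7 lists, among them the immediate early genes at 0.26 (next 0.18), and impaired replicate 5 in 6 lists. Relative to the median of the region, replicate 5 stood at 2.83 in class II (next 0.66), 0.52 in interferon response (next 0.1), 0.4 in reactive microglia (next 0.19), 0.36 in MHC class I (next 0.2), 0.33 in resting microglia (next 0.17) and 0.17 in complement (next 0.15), and it was lowest in synaptic vesicle genes at -0.15. Without it, C4b in whole hippocampus aged against adult was at 0.79 (adjusted p = 0.0153). Intact replicate 7 was lowest in 8 lists, among them endothelium at -0.27, and highest in synaptic vesicle genes at 0.49 (next 0.26). Ttr had a standard deviation of 2.48 among the adults of whole hippocampus. In adult DG, the CA1 markers Wfs1 and Ccn3 had standard deviations of 1.13 and 0.86, and in adult CA1 LOC499029 had 1.44.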
